A study of Homo sapiens with 6 samples.

How the data were processed

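RNA from 6 samples of SU-DHL-2 cells was measured, 3 labelled as control and 3 as treated with 15 µM morusinol for 12 h. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a SMARTer mRNA-seq kit. The authors deposited 1 table of FPKM values, rounded to 2 decimals, with a gene symbol and an exonic length for each of 61806 Ensembl gene IDs, all of them human; FPKM is named in the file headers. The aligner, the counter, the annotation and whether counting used strand are not given in the sources used here. The submitters' processing notes name GRCm38 and mm10, a mouse build, which does not go with human gene IDs, so the build of the table is unknown and no coordinates are given. Genes are named by the symbols and IDs of the table, and 968 tested genes have an ID only. Each sample has its own FPKM column and no column of sample values was left unused (0).

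FPKM times exonic length in kilobases summed to 999998 to 1000003 in each library, so the unit is relative to reads assigned to genes. In genes under 400 bases, 100% of the low values used were whole multiples of the value of 1 read within 0.1 reads, which gives a depth of 13.0 to 16.7 M assigned reads per library. On simulated libraries this depth was recovered with an error of at most 0.0075%. No 2 libraries were copies: the chi-square per degree of freedom of recovered reads was 2.38 to 5.48 between replicates outside Morusinol 1.

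Choices made before the data were examined were the grouping, the test, the filter, the 30 gene lists, the 6 marker lists, the rule for named genes and the first alternatives. The plan held a count test for a table of counts and limma for normalized values. As the table holds FPKM, the second applied: limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1), genes with at least 1 FPKM in at least 3 libraries, group as the only term, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Values are means ± SD over 3 libraries, and fold changes carry the SE of the limma fit. Lists with at least 5 tested members were tested by camera with a preset correlation of 0.01, again by camera with an estimated correlation, and by fry, each adjusted over the lists. Counts of members past the test are given over all genes tested and adjusted over the list alone.

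The named genes are the 10 largest rises and 10 largest falls among genes past the threshold that have a symbol, a mean of at least 1 FPKM in the higher group and no overlap between groups, the 4 members with the smallest p of each list past the set test, and the 2 with the smallest p of each other list. This gave 108 genes, some of which are not reported here. A gene outside this rule is said to have been chosen after its values were seen. The lists were cholesterol synthesis, SREBP-regulated lipid genes, LXR targets, ATF4 integrated stress response, endoplasmic reticulum chaperones and unfolded protein response, NRF2 targets, heat shock proteins, metallothioneins, p53 targets, G1/S and DNA replication, G2/M and mitosis, DNA damage checkpoint and homologous recombination, MYC-regulated ribosome biogenesis, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, NF-kB targets, B cell receptor signalling, JAK-STAT targets, interferon response, antigen presentation, immediate early genes, plasma cell programme, B cell identity and germinal centre, BCL2 family, autophagy and lysosome, glycolysis, hypoxia response, FOXO targets and aryl hydrocarbon receptor targets, and the marker lists T and NK cells, monocytes and macrophages, fibroblasts, epithelial cells, endothelial cells and B cells. A further 7 lists, chosen after the data were seen, are reported with the other observations. GENCODE 29 matched 94.3% of the IDs and was used only for gene type and GC content.

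Other settings, also chosen before the data were examined, were a pseudocount of 0.1, no filter on low values, the replicate number as a block, each library left out in turn, a test against a fold of 1.5, an estimated correlation and fry. Those planned for a table of counts (other count normalizations, other count tests and other count filters) did not apply. Added after the data were seen were array weights (limma, estimated gene by gene after the REML estimate did not converge), median-of-ratios scaling, quantile normalization, removal of a spline with 5 degrees of freedom on exonic length, limma-voom on reads recovered from FPKM and length, and a test against a fold of 1.5 without Morusinol 1.

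The test was run on simulated counts for the 11616 genes of the comparison of Morusinol with Control, turned into FPKM, with a subset of genes changed 1.5-fold, 2-fold or 4-fold. With 6 ordinary libraries it recovered 84.8% of 1.5-fold, 89.4% of 2-fold and 100% of 4-fold changes, with 7 false calls. With 1 treated library given the deviations of Morusinol 1, shuffled over genes, it recovered 1.52%, 9.86% and 63.5%, with 0 false calls. With 5 ordinary libraries it recovered 65.8%, 96.5% and 100%, with 8 false calls. All genes had the same dispersion. Shuffling removes any pattern shared by related genes, so these runs do not show what false calls such a pattern would give.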

Results

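SU-DHL-2 is an established human cell line of diffuse large B cell lymphoma, and morusinol is a flavonoid of mulberry root bark. Cells were kept for 12 h with vehicle (Control, 3 libraries) or with 15 µM morusinol (Morusinol, 3 libraries), and the comparison asks which transcripts differ after the treatment. The table gives FPKM for 61806 human Ensembl gene IDs, and 11616 genes with at least 1 FPKM in at least 3 libraries were tested. Recovered depth was 13.0 M assigned reads in Morusinol 1 and 15.4 to 16.7 M in the other 5 libraries, so that 1 read in a gene of 2000 bases was worth 0.0299 to 0.0384 FPKM. The labels do not state that the 3 libraries of a group came from separate cultures, so the per-gene p-values measure only the spread between these samples, which may be technical. Camera with its preset correlation compares the genes of a list with the other tested genes. Its small p-values therefore do not measure the spread between libraries.

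Morusinol 1 stood apart from the other libraries. Across the tested genes its Pearson correlation of log2(FPKM + 1) with the others was 0.843 to 0.863, while the other 5 libraries correlated at 0.961 or above and replicates among them at 0.991. Cytosolic ribosomal protein genes took 14.5% of its reads, against 4.28% to 4.71% in the other 5 libraries, and genes of the mitochondrial genome took 4.07%, against 8.23% to 9.98%. It had 21442 genes above 0, against 23683 to 24594. The library was doubted only after its values were seen. Leaving out each library in turn had been planned, whereas singling out this one had not. Values without it stand beside those of all 6 for the counts of calls, the gene lists and some of the genes.

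**Figure D1:**
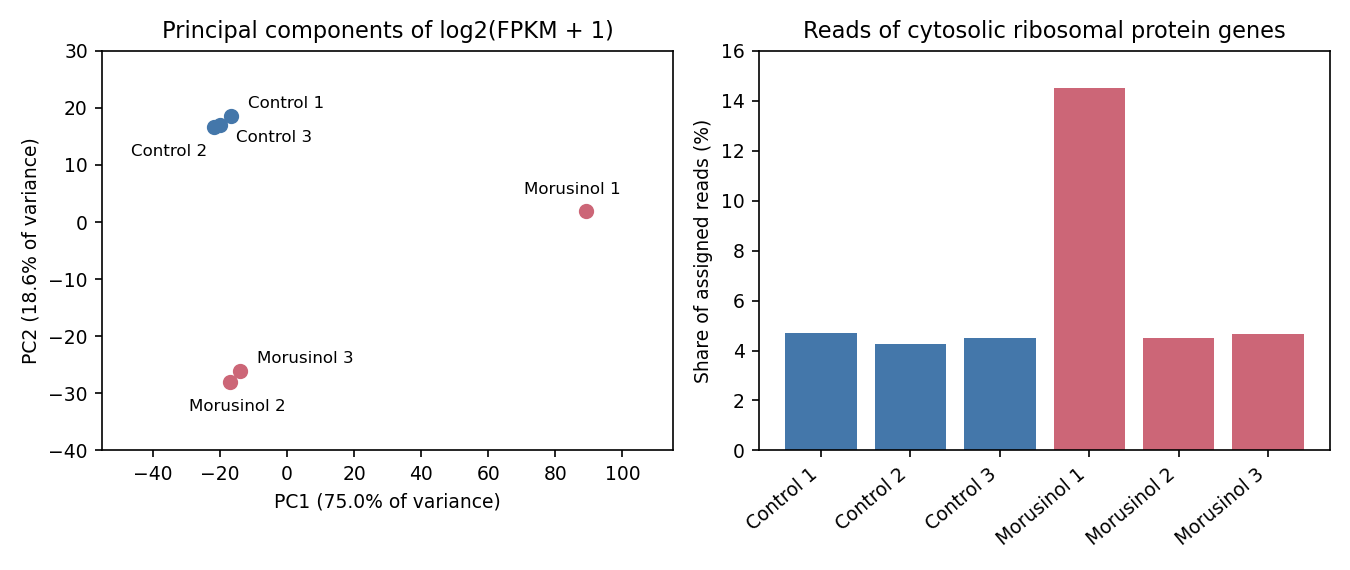
Left, the first 2 principal components of log2(FPKM + 1) over the 11616 tested genes, 1 point per library (PC1 75% and PC2 18.6% of the variance). Right, the percent of assigned reads in cytosolic ribosomal protein genes, 1 bar per library. Morusinol 1 lies apart on PC1 and has 14.5% of its reads in these genes, and PC2 parts the 3 control libraries from Morusinol 2 and Morusinol 3.

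In SU-DHL-2 cells given morusinol, 12 of 20 tested enzymes of cholesterol synthesis fell. Of 24 targets of the stress response factor ATF4 15 rose, as did 5 of 18 endoplasmic reticulum chaperone and unfolded protein response genes. Of 35 genes of the G1/S transition and DNA replication 14 fell. These counts are by limma-trend with all 6 libraries, adjusted over all genes tested. HMGCS1, which makes HMG-CoA for the mevalonate pathway, went from 54.9 ± 2.41 to 9.24 ± 0.335 FPKM (SD, n = 3 per group; log2 fold change -2.45 ± 0.11 SE, adjusted p = 0.00228, limma-trend). CTH, which makes cysteine from cystathionine, rose from 0.400 ± 0.0889 to 20.3 ± 1.08 FPKM (SD, n = 3; log2 fold change 3.93 ± 0.12 SE, adjusted p = 3.75e-04). CHAC1, which degrades glutathione, rose from 0.533 ± 0.0603 to 16.8 ± 0.248 FPKM (SD, n = 3; log2 fold change 3.54 ± 0.11 SE, adjusted p = 3.75e-04). The replication factor MCM10 fell from 17.1 ± 0.248 to 4.82 ± 1.44 FPKM (SD, n = 3), with a log2 fold change of -1.67 ± 0.21 SE (limma-trend adjusted p = 0.0201). With Morusinol 1 left out, the log2 fold changes of HMGCS1, CTH, CHAC1 and MCM10 were -2.42, 3.97, 3.54 and -1.45.

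The other 8 of the 10 largest rises were CCL3L1, CCL3, PLAU, PSAT1, SLC7A11, DDIT3, ASS1 and TRIB3, with log2 fold changes from 3.37 down to 2.52. PSAT1, of serine synthesis, rose from 38.6 ± 0.803 to 268 ± 59.2 FPKM, and PLAU, a secreted protease that activates plasminogen, from 6.54 ± 0.610 to 50.7 ± 6.30 FPKM. The arginine synthesis enzyme ASS1 rose from 0.377 ± 0.110 to 6.95 ± 0.388 FPKM, and SLC7A11, the cystine importer, from 2.42 ± 0.145 to 22.3 ± 7.70 FPKM (all SD, n = 3). DDIT3, which encodes CHOP, had 96.2 FPKM in Morusinol 1 against 32.5 and 35.4 FPKM in Morusinol 2 and 3, and 6.95 ± 1.09 FPKM in control (SD, n = 3). CCL3 and CCL3L1 encode near-identical chemokines, so the division of reads between them is uncertain. With Morusinol 1 left out, the log2 fold changes of CCL3, CCL3L1 and DDIT3 were 2.86, 2.98 and 2.14. Besides HMGCS1 and MCM10, the largest falls included ACAT2, MSMO1, UHRF1, SQLE, RRM2 and C11orf53, with log2 fold changes from -2.02 to -1.55. UHRF1, which guides maintenance DNA methylation, fell from 27 ± 1.38 to 7.40 ± 0.794 FPKM, and C11orf53 from 15.2 ± 1.17 to 4.53 ± 0.0985 FPKM (SD, n = 3). In the file HMGCS1 is ENSG00000112972, CTH is ENSG00000116761, CHAC1 is ENSG00000128965 and MCM10 is ENSG00000065328.

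**Figure D2:**
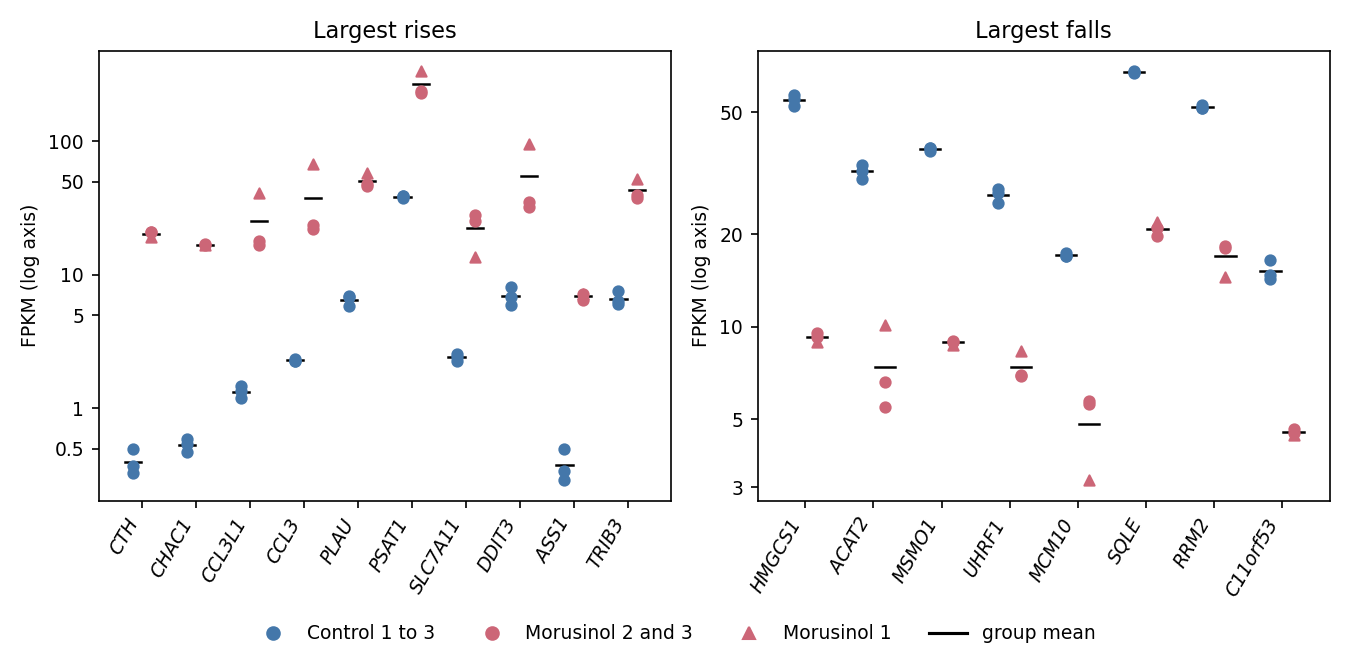
FPKM on a log axis of the 10 genes with the largest rise (left) and 8 of the 10 with the largest fall (right), 1 point per library, with Morusinol 1 as a triangle and black lines at the group means. The treated and control libraries of each of these genes did not overlap, which was a condition for naming them. Morusinol 1 lies farthest above the other treated libraries in CCL3, CCL3L1 and DDIT3. It is also above them in PSAT1, PLAU, TRIB3 and ACAT2, among others, and below them in genes such as SLC7A11 and MCM10.

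With all 6 libraries, 214 genes were higher and 119 lower with morusinol at an adjusted p under 0.05 (limma-trend on log2(FPKM + 1), Benjamini-Hochberg), 136 and 54 of them by at least 2-fold. Control and treated values did not overlap in any of these 333 genes. The same held for 4142 of the 11616 tested genes, these included (35.7%, against 10% by chance for 3 against 3). By limma-trend 2029 of the 11616 tested genes had an unadjusted p under 0.05, and such counts in the lists are to be read against that share. Without Morusinol 1, 2708 genes were higher and 2650 lower, 266 and 98 by at least 2-fold. Together these were 5358 of the 11616 tested genes, so a list with a like share of calls without Morusinol 1 does not stand out. All 214 and 119 were called in the same direction there, and 0 were called in opposite directions. The other libraries mattered as well: 18 genes were higher and 2 lower without Morusinol 2, and 17 and 4 without Morusinol 3. CTH and CHAC1 alone were called without Control 1, without Control 2 or without Control 3, where 2 were higher and 0 lower each time, with 1142, 1154 and 1141 genes at an unadjusted p under 0.05. Other settings gave 101 higher and 57 lower without a filter, 21 and 6 against a fold of 1.5, 370 and 274 after quantile normalization, 490 and 392 after length correction, 296 and 233 after median-of-ratios scaling, and 2938 and 2868 with array weights. The replicate number as a block, a pairing that the labels do not name, gave 0 higher and 0 lower. By limma-trend 1467 genes had an unadjusted p under 0.05 there.

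Cholesterol synthesis was lower as a group. Of its 20 tested enzymes 12 fell and 0 rose over all genes tested, and 17 fell when adjusted over the list alone (median log2 fold change -1.32, camera adjusted p = 6.33e-17). The call held with an estimated correlation (adjusted p = 0.00865). The squalene epoxidase SQLE fell from 67.7 ± 0.410 to 20.9 ± 1.10 FPKM and the sterol oxidase MSMO1 from 37.9 ± 0.556 to 8.89 ± 0.136 FPKM (SD, n = 3). Without Morusinol 1, 19 of the 20 fell and the median was -1.26. The set passed camera there with its preset correlation (adjusted p = 1.45e-13), but not with an estimated correlation (adjusted p = 0.119). No list passed camera with an estimated correlation without this library. The exception was PMVK, chosen after its values were seen, at 15.0 ± 0.509 FPKM in control and 71.6, 14.8 and 14.7 FPKM in the 3 treated libraries.

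Among 12 other lipid genes under SREBP control, the cholesterol carrier STARD4 fell (log2 fold change -0.87 ± 0.15 SE, adjusted p = 0.0446) and 11 did not pass over all genes, while 8 were lower when adjusted over the list alone. The list was lower as a group (median -1.05, camera adjusted p = 5.20e-05), but not past the threshold with an estimated correlation (adjusted p = 0.314 with an estimated correlation). The desaturases SCD and FADS2 went from 186 ± 4.58 to 61.5 ± 23.6 FPKM and from 52.0 ± 1.30 to 14.0 ± 6.73 FPKM (SD, n = 3), with adjusted p = 0.0636 and 0.0668; both were lowest in Morusinol 1, at 34.3 and 6.21 FPKM. INSIG1, which retains SREBP in the endoplasmic reticulum, had a log2 fold change of -0.71 (adjusted p = 0.0745). Without Morusinol 1, 9 of the 12 fell, SCD, FADS2 and INSIG1 among them, and SREBF1 rose (log2 fold change 0.51, adjusted p = 0.00102). Of 4 tested LXR targets, too few for a set test, 0 passed with all 6 libraries in either count, 1 having an unadjusted p under 0.05. SMPDL3A and SREBF1 had log2 fold changes of 0.60 and 0.29, and both rose without Morusinol 1 (0.43 and 0.51).

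Targets of ATF4, the transcription factor of the integrated stress response, were higher. Of 24 tested genes 15 rose and 0 fell over all genes, 22 rose when adjusted over the list alone, and all 24 had positive fold changes (median 1.83, camera adjusted p = 3.97e-27). The call held with an estimated correlation (adjusted p = 0.00696). DDIT4, an inhibitor of mTORC1 signalling, rose from 1.55 ± 0.0635 to 10.1 ± 1.27 FPKM, and the pseudokinase TRIB3 from 6.66 ± 0.835 to 43.2 ± 7.90 FPKM (SD, n = 3). ATF4 itself, chosen after its values were seen, had 68.3 ± 0.818 FPKM in control and 177 ± 64.3 FPKM in treated libraries (SD, n = 3; adjusted p = 0.0639). Without Morusinol 1 all 24 rose, ATF4 included (log2 fold change 1.03, adjusted p = 1.31e-05). The set passed camera there with its preset correlation (adjusted p = 1.78e-18), but not with an estimated correlation (adjusted p = 0.0785).

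Chaperones and degradation factors of the endoplasmic reticulum were also higher, with 5 of 18 tested genes rising, 12 when adjusted over the list alone, and a camera adjusted p = 2.02e-12 that held with an estimated correlation (adjusted p = 0.00970). The 5 were HERPUD1 (log2 fold change 1.95), EDEM1 (from 7.20 ± 0.665 to 32.1 ± 5.61 FPKM), DNAJC3 (log2 fold change 1.16), DNAJB9 (1.56) and DNAJB11 (0.81), the last outside the naming rule and chosen after its values were seen. HERPUD1 and EDEM1 act in the disposal of misfolded proteins, and the other 3 are DnaJ co-chaperones. Without Morusinol 1 all 18 rose. The set passed camera there with its preset correlation (adjusted p = 5.3e-13), but not with an estimated correlation (adjusted p = 0.0785). Among 25 autophagy and lysosome genes 4 rose and 0 fell, 15 when adjusted over the list alone (median 0.55, camera adjusted p = 2.67e-09, and 0.0225 as the adjusted p with an estimated correlation). They were the autophagy receptor SQSTM1 (from 11.3 ± 0.858 to 56.5 ± 15.1 FPKM), MAP1LC3B (from 16.4 ± 0.906 to 36.6 ± 7.07 FPKM) and the cathepsins CTSB and CTSD, with log2 fold changes of 0.89 and 1.08. Without Morusinol 1, 20 of these 25 rose and 0 fell. This set too passed camera there with its preset correlation (adjusted p = 7.60e-09), but not with an estimated correlation (adjusted p = 0.128).

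Of 12 NRF2 targets 2 rose, namely the haem oxygenase HMOX1 (from 2.54 ± 0.197 to 8.95 ± 1.47 FPKM, SD, n = 3) and SLC7A11, which is also in the ATF4 list, and 4 rose when adjusted over the list alone. The set test passed (camera adjusted p = 0.0202) but not with an estimated correlation (adjusted p = 0.178 with an estimated correlation) nor with array weights (adjusted p = 0.0775) or without Morusinol 1 (adjusted p = 0.0948), where 7 rose and 3 fell. FTH1, whose many pseudogenes make its reads uncertain, and GCLM had log2 fold changes of 0.91 and 0.44 and did not pass with all 6 libraries. Heat shock proteins leaned the other way: HSPH1 fell from 124 ± 5.12 to 63.2 ± 6.72 FPKM (SD, n = 3), 1 of 14 genes over all genes and 5 when adjusted over the list alone (camera adjusted p = 0.0347; adjusted p = 0.293 with an estimated correlation). That call was lost without Control 2, Morusinol 2 or Morusinol 3 (adjusted p = 0.0574, 0.194 and 0.177), after median-of-ratios scaling (0.143), after length correction (0.0797) and with the replicate number as a block (0.0971). Without Morusinol 1, 10 fell and 2 rose. HSP90AA1, DNAJB1 and HSPA8 had log2 fold changes of -0.64, -0.52 and -0.68, the reads of HSPA8 being uncertain because of its pseudogenes. Metallothionein genes passed the set test (camera adjusted p = 0.0317) with 0 of 7 members called in either count and 2 at an unadjusted p under 0.05. The call was lost with an estimated correlation (adjusted p = 0.378 with an estimated correlation) and without Morusinol 1 (adjusted p = 0.173), as well as with array weights, median-of-ratios scaling, quantile normalization, length correction and fry (adjusted p = 0.147, 0.107, 0.0853, 0.0797 and 0.228). MT1F, MT1G and MT1E, close paralogs, had 11.9, 12.9 and 18.0 FPKM in Morusinol 1 against at most 3.30, 4.86 and 3.21 FPKM in Morusinol 2 and 3, and the zinc exporter SLC30A1 had a log2 fold change of -0.40, or -0.20 without Morusinol 1.

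Genes of the G1/S transition and DNA replication were lower. Of 35 tested genes 14 fell and 0 rose over all genes, 25 fell when adjusted over the list alone, and all 35 had negative fold changes (median -0.96, camera adjusted p = 3.50e-18), a call that held with an estimated correlation (adjusted p = 0.00723). The ribonucleotide reductase subunit RRM2 fell from 52.1 ± 0.642 to 17.0 ± 2.13 FPKM, the helicase subunit MCM4 from 47.1 ± 0.723 to 19.1 ± 1.43 FPKM and cyclin E1, CCNE1, from 26.0 ± 0.469 to 9.31 ± 1.52 FPKM (SD, n = 3). The transcription factor E2F2 fell from 2.65 ± 0.107 to 0.577 ± 0.145 FPKM (SD, n = 3). Without Morusinol 1 all 35 fell. The set passed camera there with its preset correlation (adjusted p = 2.25e-19), but not with an estimated correlation (adjusted p = 0.0785). Mitotic genes were lower by less: cyclin A2, CCNA2, fell (log2 fold change -0.89 ± 0.13 SE, adjusted p = 0.0327), 1 of 27 in both counts, with a list median of -0.31 (camera adjusted p = 0.0202; adjusted p = 0.204 with an estimated correlation). DLGAP5, KIF11 and TTK had log2 fold changes of -0.43, -0.47 and -0.24 and did not pass; that of KIF11 was -0.31 without Morusinol 1. The mitotic call was lost without Morusinol 2 or Morusinol 3 (adjusted p = 0.0611 and 0.0505). Without Morusinol 1, 16 of the 27 fell, DLGAP5, KIF11 and TTK among them.

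Among 26 genes of the DNA damage checkpoint and homologous recombination, the nuclease EXO1 fell from 15.8 ± 0.437 to 5.23 ± 1.10 FPKM and the checkpoint kinase CHEK1 from 27.9 ± 1.10 to 15.6 ± 0.478 FPKM (SD, n = 3), 2 over all genes and 8 when adjusted over the list alone. The list passed the set test (median -0.60, camera adjusted p = 3.24e-07; adjusted p = 0.174 with an estimated correlation). CLSPN and BARD1 had log2 fold changes of -1.56 and -0.87 and did not pass. Without Morusinol 1, 19 fell, CLSPN and BARD1 among them, and 1 rose. MYC-regulated ribosome biogenesis genes also passed as a set (median -0.28, camera adjusted p = 0.0159; adjusted p = 0.151 with an estimated correlation), with 0 of 26 called in either count and 5 at an unadjusted p under 0.05. That call was lost without Morusinol 2 or Morusinol 3 (adjusted p = 0.0858 and 0.0619), and without Morusinol 1, 22 fell and 0 rose. The nucleolar proteins NOP58, NOP56, WDR12 and NCL had log2 fold changes of -0.50, -0.71, -0.35 and -0.57, that of NCL being -0.37 without Morusinol 1. Targets of p53 passed in the other direction (median 0.18, camera adjusted p = 0.0290; adjusted p = 0.178 with an estimated correlation), with 0 of 17 called in either count and 3 at an unadjusted p under 0.05. The call was lost without Morusinol 2 (adjusted p = 0.0639). PMAIP1 and BBC3, which encode the death factors NOXA and PUMA, had log2 fold changes of 1.02 and 0.71, and GADD45A and FAS had 0.82 and 0.23. Without Morusinol 1, 9 of the 17 rose, these 4 included, and 2 fell. BBC3 and GADD45A rose by less than with all 6 libraries (log2 fold changes 0.42 and 0.50). The 2 that fell were CDKN1A and XPC, chosen after their values were seen, with log2 fold changes of -0.15 and -0.18.

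NF-kB targets moved both ways. CCL3, CCL4 and the cytokine LTA rose, BIRC3 and CCL22 fell, and 19 of 24 did not pass over all genes; the counts were 5 higher and 3 lower when adjusted over the list alone. LTA rose from 70.2 ± 5.04 to 183 ± 10.6 FPKM, and CCL4, whose reads its copy CCL4L2 makes uncertain, from 0.110 ± 0.0173 to 3.54 ± 1.10 FPKM (SD, n = 3). The apoptosis inhibitor BIRC3 fell from 34.0 ± 0.604 to 13.0 ± 3.41 FPKM and the chemokine CCL22 from 2.85 ± 0.277 to 0.680 ± 0.145 FPKM (SD, n = 3), both chosen after their values were seen. The list did not pass the set test (camera adjusted p = 0.276), and its median of -0.00243 and mean of 0.23 differed in sign, the test direction being up. Without Morusinol 1, 12 rose and 8 fell, with a median of 0.15. Of 20 B cell receptor genes 0 passed in either count, with 5 at an unadjusted p under 0.05 (camera adjusted p = 0.705). BLNK and PTPN6, an adaptor and a phosphatase of that pathway, had log2 fold changes of 0.63 and 0.54, and without Morusinol 1, 7 rose and 5 fell, with a set direction of up (adjusted p = 0.937) beside a median of -0.02 and a mean of 0.02.

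In the plasma cell list SLAMF7 rose from 1.61 ± 0.191 to 9.16 ± 1.85 FPKM and the chaperone-like FKBP11 from 6.66 ± 0.639 to 15.8 ± 1.29 FPKM, while CD27, chosen after its values were seen, fell from 8.68 ± 0.583 to 5.18 ± 0.121 FPKM (SD, n = 3), a call that limma-voom on recovered reads did not give. These were the 3 of 10 that passed over all genes, against 5 higher and 2 lower when adjusted over the list alone, and camera did not pass (adjusted p = 0.125) while fry did (adjusted p = 1.64e-05). Without Morusinol 1, 5 rose and 4 fell. Genes of B cell identity and the germinal centre passed as a set (median -0.36, camera adjusted p = 0.0293; adjusted p = 0.178 with an estimated correlation). SPIB, a B cell transcription factor, fell from 5.60 ± 0.569 to 2.50 ± 0.257 FPKM (SD, n = 3), 1 of 14 over all genes and 3 when adjusted over the list alone. MYBL1 and LMO2 had log2 fold changes of -0.66 and -0.97. The set call was lost without Morusinol 2 or Morusinol 3 (adjusted p = 0.0720 and 0.0505) and after median-of-ratios scaling (adjusted p = 0.0504), and without Morusinol 1, 7 fell and 1 rose, with a median of -0.23.

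Immediate early genes passed the set test (median 0.43, camera adjusted p = 0.00108; adjusted p = 0.0953 with an estimated correlation), with 0 of 11 called over all genes, 4 higher when adjusted over the list alone and 5 at an unadjusted p under 0.05. EGR1 had 0.477 ± 0.0751 FPKM in control and 2.95 ± 1.24 FPKM in treated libraries (SD, n = 3), and IER3, ZFP36 and ATF3 had log2 fold changes of 0.86, 1.09 and 0.86; without Morusinol 1, 8 rose, these 4 included, and 1 fell. Of 9 JAK-STAT targets 0 passed over all genes, 1 was lower when adjusted over the list alone and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.312). BCL3 and STAT3 had log2 fold changes of -1.13 and -1.24, and without Morusinol 1, 2 of the 9 rose and 3 fell. Neither the 5 tested interferon genes nor the 13 of antigen presentation held a call in either count or a member at an unadjusted p under 0.05 (camera adjusted p = 0.822 and 0.312). For the interferon list the median was -0.13, the mean 0.10 and the camera direction up, while fry and camera without a filter gave down. IRF7, ISG15 and HLA-B had log2 fold changes of 0.40, 0.77 and 0.79, and each was highest in Morusinol 1, as in ISG15 with 62.0 FPKM there and at most 12.2 FPKM in Morusinol 2 and 3. Without Morusinol 1 the log2 fold changes of these 3 were 0.19, 0.00 and 0.25, the interferon list held 0 calls with a median of 0.06, and the antigen presentation list 2 higher and 1 lower. In the BCL2 family 0 of 13 passed in either count, with 5 at an unadjusted p under 0.05 (camera adjusted p = 0.174; by fry, adjusted p = 0.00626). BCL2, an apoptosis inhibitor, had 7.29 ± 0.140 FPKM in control (SD, n = 3) and 8.16, 19.7 and 18.7 FPKM in the treated libraries, and without Morusinol 1, 5 of the 13 rose, BCL2 and PMAIP1 included, and 3 fell.

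Glycolysis genes were lower as a set (median -0.57, camera adjusted p = 1.31e-04; adjusted p = 0.314 with an estimated correlation). None of the 17 was called over all genes, 0 higher and 0 lower, 3 were lower when adjusted over the list alone and 7 had an unadjusted p under 0.05. PGAM1 and LDHA, a glycolytic mutase and lactate dehydrogenase, went from 73.5 ± 1.87 to 48.1 ± 0.676 FPKM and from 296 ± 4.18 to 172 ± 27.1 FPKM (SD, n = 3), and PFKFB3 and ALDOC had log2 fold changes of -0.71 and -0.66. Without Morusinol 1, 16 fell, these 4 included, and 1 rose, and the median was -0.27. In the hypoxia list BNIP3L, a mitophagy receptor, rose from 5.07 ± 0.0458 to 9.34 ± 0.119 FPKM (SD, n = 3), 1 of 10 over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.0317; adjusted p = 0.320 with an estimated correlation). VEGFA, INSIG2 and SLC2A1 had log2 fold changes of 1.06, 0.61 and -0.47, that of SLC2A1 being -0.24 without Morusinol 1. The call was lost without Morusinol 2 or Morusinol 3 (adjusted p = 0.10 and 0.0619) and without a filter on low values (adjusted p = 0.118), and without Morusinol 1, 5 rose and 1 fell. FOXO targets went both ways: CCNG2 and CDKN1B rose (log2 fold changes 0.98 and 1.06) and TXNIP fell (-0.88), CDKN1B having been chosen after its values were seen. These 3 of 11 passed over all genes, 2 higher and 2 lower when adjusted over the list alone, and the set test did not (camera adjusted p = 0.822; median -0.01, mean 0.04, test direction up, and down without Morusinol 3). Without Morusinol 1, 6 rose and 4 fell, with a median of 0.18. Of 4 targets of the aryl hydrocarbon receptor, too few for a set test, 0 passed in either count and 1 had an unadjusted p under 0.05. CYP1A1 and NQO1 had log2 fold changes of 0.75 and 0.40, and without Morusinol 1 all 4 rose, NQO1 with 0.20.

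Ribosomal protein and oxidative phosphorylation genes followed Morusinol 1. The 76 cytosolic ribosomal protein genes had a median log2 fold change of 0.57 with all 6 libraries (camera adjusted p = 2.16e-07; adjusted p = 0.574 with an estimated correlation) and of 0.01 without that library (adjusted p = 0.679). They did not pass with array weights or fry either (adjusted p = 0.686 and 0.417). None was called with all 6 in either count or had an unadjusted p under 0.05, and 5 rose and 2 fell without Morusinol 1. RPL12, RPL3, RPL10 and RPS27, whose reads are uncertain because of processed pseudogenes, had log2 fold changes of 0.43, 0.26, 0.57 and 0.61, and 0.24, 0.17, 0.17 and 0.17 without Morusinol 1, that of RPL3 turning to -0.02 under quantile normalization. The 42 nuclear-encoded oxidative phosphorylation genes had a median of 0.35 with all 6 libraries (camera adjusted p = 0.0290, up; adjusted p = 0.700 with an estimated correlation). Without Morusinol 1 the median was -0.12 and the set direction down (adjusted p = 9.88e-04), with 17 falling, 0 rising and no call with an estimated correlation (adjusted p = 0.549). It was down with array weights too (adjusted p = 0.00401), and did not pass after median-of-ratios scaling, quantile normalization or length correction or by fry (adjusted p = 0.0504, 0.110, 0.10 and 0.671). With all 6, 0 of the 42 passed in either count or at an unadjusted p under 0.05; NDUFA10, NDUFA5, CYC1 and NDUFS1 had log2 fold changes of -0.19, 0.35, -0.72 and -0.30. Without Morusinol 1 these were -0.20, 0.14, -0.14 and -0.06. The 13 mRNAs of the mitochondrial genome, MT-ND6 and MT-ND1 (log2 fold changes -0.34 and -0.57, or -0.13 and -0.09 without Morusinol 1) among them, held 0 calls in either count and 0 at an unadjusted p under 0.05. Their median was -0.57 with all 6 libraries (camera adjusted p = 0.107) and -0.04 without Morusinol 1, where 0 were called as well, and without Morusinol 3 the set passed (adjusted p = 0.0401).

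Of 28 lists with at least 5 tested members, 19 passed camera with its preset correlation, 10 higher and 9 lower, and 5 passed with an estimated correlation: cholesterol synthesis, ATF4 targets, endoplasmic reticulum chaperones, G1/S genes, and autophagy and lysosome genes. By fry 18 passed; its PValue tests whether the genes of a set move, on balance, one way, and does not compare the set with other genes or sets. Without Morusinol 1, 16 lists passed camera, 6 higher and 10 lower, 22 passed fry and 0 passed with an estimated correlation, the lowest adjusted p being 0.0785 and 7 having an unadjusted p under 0.05. With an estimated correlation camera works on the residual degrees of freedom, which are fewer when a library is left out. Part of this loss of calls may come from that. In the 15 lists without a called member, limma-voom on recovered reads likewise called 0 of 277 tested members. Of these members 37 had an unadjusted p under 0.05 in the main test, against 2029 of all 11616 tested genes, which is a larger share. A gene in more than 1 of these lists was counted once for each.

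**Figure D3:**
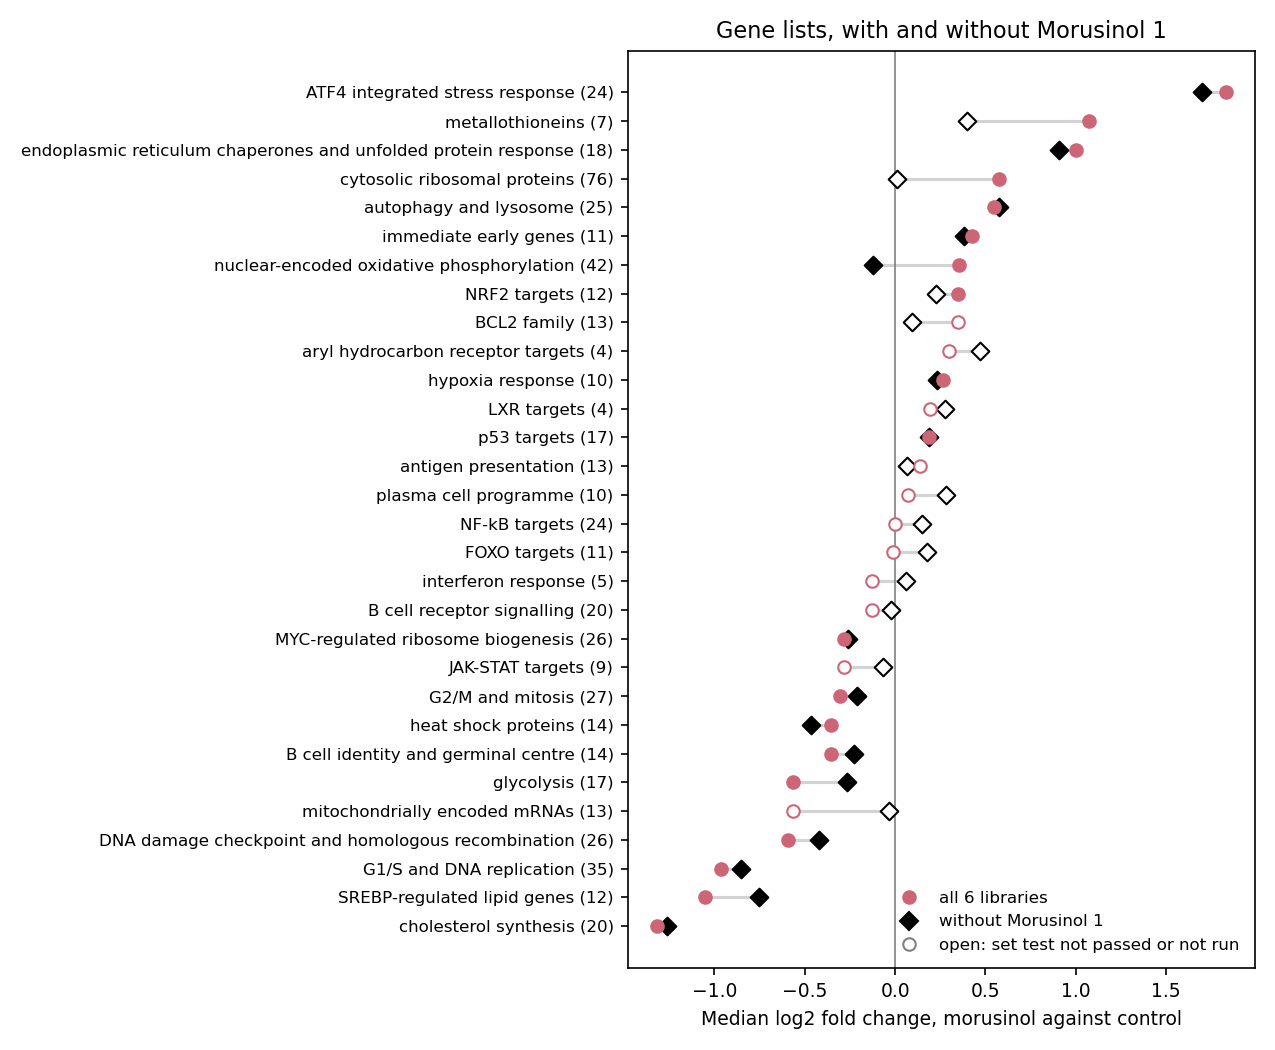
Median log2 fold change of the tested members of each list, with the number of members in parentheses, for all 6 libraries (circles) and without Morusinol 1 (diamonds); filled symbols passed camera at an adjusted p under 0.05. Cholesterol synthesis (-1.32 and -1.26) and ATF4 targets (1.83 and 1.70) lie at the 2 ends with and without that library, and oxidative phosphorylation goes from 0.35 to -0.12.

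Markers of B cells were present in every library, with all 6 at 1 FPKM or more and MS4A1 at up to 235 FPKM. The highest value of any of 9 T and NK cell markers was 0.52 FPKM, of 9 monocyte and macrophage markers 0.48 FPKM, of 6 fibroblast markers 0.11 FPKM and of 4 endothelial markers 0.15 FPKM. Among 5 epithelial markers EPCAM reached 1 FPKM, with 2.20 to 2.51 FPKM in the control libraries, 4.99 FPKM in Morusinol 1 and 1.68 and 1.75 FPKM in Morusinol 2 and Morusinol 3.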

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

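Array weights, the 3 other scalings (median of ratios, quantile, length), limma-voom on recovered reads and the fold test without Morusinol 1 were chosen after the data were seen. Under a pseudocount of 0.1 and limma-voom all counts stayed within 1.5 times (209 higher and 103 lower, and 235 and 118). Without a filter 101 were higher and 57 lower, 118 by at least 2-fold. Against a fold of 1.5 the numbers were 21, 6 and 27, and with array weights, which gave Morusinol 1 a weight of 0.0153, 2938, 2868 and 370. Quantile normalization gave 370 higher and 274 lower and length correction 490 and 392, while median-of-ratios scaling gave 233 lower. The fold test without Morusinol 1 called 316 by at least 2-fold. Leaving out 1 library at a time gave 2 to 2708 higher, 0 to 2650 lower, 2 to 364 by at least 2-fold and 13 to 19 lists. An estimated correlation left 5 lists and fry 18. For these differences the cause was not tested.

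The replicate number as a block gave 0 higher, 0 lower and 0 by at least 2-fold by limma-trend, with 1467 genes at an unadjusted p under 0.05, and 18 lists, heat shock proteins no longer passing (adjusted p = 0.0971). Deviations from the group means of same-numbered libraries correlated at 0.229, 0.197 and 0.0218, and Morusinol 3 correlated best with Control 2 (0.183). Morusinol 1 sets the treated mean in these deviations, so they say little on the other 2 pairs. The differences between replicates 2 and 3, a check chosen after the data were seen, correlated at 0.0225 between the groups. The labels name no pairing, and whether the numbers pair the samples stays open.

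Directions turned in 8 instances. RPL3 had a log2 fold change of -0.0231 under quantile normalization. Oxidative phosphorylation was lower without Morusinol 1 (adjusted p = 9.88e-04) and with array weights (0.00401), and B cell receptor genes were up there (0.937 and 0.909). The interferon list was down without a filter (0.526) and by fry (0.934), and FOXO targets without Morusinol 3 (0.997). Leaving out 1 library at a time gave adjusted p of 1.43e-04 to 0.0448 for oxidative phosphorylation, 0.440 to 0.937 for B cell receptor genes and 0.614 to 0.997 for FOXO targets. The 46 named genes that passed kept their direction in every setting. Of these, 46 passed with a pseudocount of 0.1, array weights, limma-voom and without Morusinol 1, 45 with quantile normalization or length correction, 42 with median-of-ratios scaling, 41 in the fold test without Morusinol 1, 36 without a filter, 15 against a fold of 1.5, 10 without Morusinol 2, 9 without Morusinol 3, 2 without any 1 control library and 0 with the block. The planned count normalizations, count tests and count filters were not run, as the table holds FPKM. Depth limits low genes: 1 read in 2000 bases is worth 0.0299 to 0.0384 FPKM.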

Other observations

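The 7 lists in the first 2 paragraphs, and the tests of a mislabelled library, of other cells, of exonic length, of Morusinol 1 alone and of fewer cycling cells, were chosen after the results were seen. Some genes that load and import amino acids rose, but these 2 lists share AARS1, GARS1, WARS1, SLC3A2, SLC7A5 and SLC7A11 with the ATF4 list and in part repeat its result. Of 20 cytosolic aminoacyl-tRNA synthetases 4 rose and 0 fell, 7 when adjusted over the list alone: CARS1 (from 6.62 ± 0.240 to 21.5 ± 1.64 FPKM), SARS1, TARS1 and WARS1, with log2 fold changes of 1.25, 0.67 and 2.13 for the last 3 (camera adjusted p = 5.89e-04; adjusted p = 0.346 with an estimated correlation). Of 16 mitochondrial synthetases 0 passed limma-trend in either count, 3 had an unadjusted p under 0.05 and limma-voom called 0 (camera adjusted p = 0.0362, down; adjusted p = 0.236 with an estimated correlation). Of 15 amino acid transporters 6 rose in both counts, namely SLC1A4, SLC1A5, SLC3A2, SLC7A11, SLC38A2 and SLC43A1 (camera adjusted p = 1.08e-05; adjusted p = 0.236 with an estimated correlation). SLC43A1 rose from 17.5 ± 0.675 to 56.6 ± 4.26 FPKM and SLC3A2 from 29.9 ± 2.80 to 95.3 ± 14.6 FPKM (SD, n = 3). Without Morusinol 1, 12 cytosolic synthetases rose and 3 fell, 1 mitochondrial synthetase rose and 7 fell, and 11 transporters rose and 0 fell (camera adjusted p = 2.48e-04, 0.0271 and 2.81e-07; adjusted p = 0.309, 0.309 and 0.112 with an estimated correlation).

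Replication-coupled chromatin genes fell with the G1/S genes: CHAF1A and CHAF1B of the histone chaperone CAF-1, ASF1B, HELLS and UHRF1, 5 of 11 in both counts, with all 11 fold changes negative (median -0.91, camera adjusted p = 1.72e-06, and 0.0394 with an estimated correlation). CHAF1A fell from 30.1 ± 0.361 to 12.2 ± 2.69 FPKM and ASF1B from 28.0 ± 0.941 to 14.2 ± 0.758 FPKM (SD, n = 3). Among 20 actin and serum response factor genes, all with negative fold changes, ACTB fell from 1412 ± 28.8 to 701 ± 36.1 FPKM (SD, n = 3), 1 in both counts (camera adjusted p = 1.83e-05; adjusted p = 0.206 with an estimated correlation). Of 9 chemokines CCL3, CCL3L1, CCL4, CCL4L2 and CXCL8 rose and CCL22 fell, 6 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.00222; adjusted p = 0.236 with an estimated correlation), the first 4 being near-identical copies in pairs with uncertain reads. CXCL8 rose from 0.847 ± 0.0907 to 6.60 ± 2.02 FPKM (SD, n = 3). Of 8 late endosome lipid genes 0 passed limma-trend over all genes, 2 were higher when adjusted over the list alone, 3 had an unadjusted p under 0.05 and limma-voom called 0 (camera adjusted p = 0.0931; adjusted p = 0.236 with an estimated correlation). Without Morusinol 1 all 4 lists passed camera with its preset correlation: 10 chromatin genes fell and 0 rose, 16 actin genes fell and 1 rose, 6 chemokines rose and 2 fell, and 4 late endosome genes rose and 1 fell (adjusted p = 2.30e-06, 2.30e-06, 0.0436 and 0.0449). None did so with an estimated correlation (adjusted p = 0.0885, 0.0885, 0.209 and 0.318 with an estimated correlation). UHRF1 was already among the largest falls, and CCL3 and CCL3L1 among the largest rises. CCL3, CCL4 and CCL22 are also in the NF-kB list, and NPC1, NPC2, LAMP1 and LAMP2 in the autophagy and lysosome list. The chromatin, chemokine and late endosome lists thus in part repeat earlier results.

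Morusinol 1 stood apart, with 14.5% of reads in ribosomal protein genes. A mislabelled control library is argued against: of 368 genes changed at least 2-fold without Morusinol 1 and Control 1, 311 (84.5%) went in the treated direction in Morusinol 1. RNA of T and NK, myeloid, fibroblast, endothelial or epithelial cells is argued against by a second most abundant marker of at most 0.27 FPKM there, although EPCAM alone was at 4.99 FPKM, and other cells of the B lineage were not tested. A trend with exonic length does not account for it alone, as the SD of its deviation fell only from 0.986 to 0.903 after correction, 4.30 times the 0.210 between Morusinol 2 and 3. The trend was present all the same: length took 16.3% of the variance of the deviation (Spearman -0.344 across genes). The median deviation was 0.553 log2 in genes of 1000 to 2000 bases and -0.719 in those over 8000 bases. In genes under 1000 bases it was -0.128. A difference in RNA quality or library preparation could remain and was not tested, nor was any biological explanation.

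Cholesterol synthesis genes were lower and ATF4 targets higher with and without Morusinol 1, though without it neither list passed camera with an estimated correlation (adjusted p = 0.119 and 0.0785). A bias of GC content and exonic length is argued against: without Morusinol 1 their trend took 0.846% of the variance of fold changes, with an SD of 0.0381 on the log2 scale over genes, and the smaller of the 2 absolute medians was 1.31 after its removal. Morusinol 1 alone is argued against by a smaller absolute median of 1.26 without it. A response of the cells to morusinol may account for both, as a hypothesis found and tested in the same data.

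G1/S genes were lower by more than mitotic genes. Matched lists of like level and length argue against those properties as the cause: 0 of 10000 draws gave as large a gap without Morusinol 1, a share of at most 0.01%, the largest gap in the draws being 0.410 against an observed -0.67. Fewer cycling cells cannot be told apart from a change within cells. The G1/S minus mitosis difference of the treated libraries lay at least 0.438 below that of the controls on the log2 scale, but both lists were lower, and the level of either in non-cycling cells was not measured. A longer stay before S phase could give the same values and was not tested.

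Other splits of the 6 libraries into 3 and 3 are 10 with the real one, too few for a share under 0.05. The real split gave 214 higher, 119 lower, 190 changed at least 2-fold and 19 lists, and the highest of the others 0, 0, 0 and 11. In each case 1 split, the real one, gave a result as large. Every other split passed 7 to 11 lists while it called 0 genes, so camera with its preset correlation also passes lists in splits that mix the groups. Those splits still carry part of the difference between groups and of Morusinol 1.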
